A study of Mus musculus with 8 samples.

How the data were processed

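RNA was measured in 8 libraries of mouse dendritic cells, 2 for each combination of genotype (Gata1 knock-out, KO, or wild type, WT) and treatment (steady state or LPS). Per the labels' protocols, RNA was purified with an RNeasy plus mini kit and libraries were made with a TruSeq RNA v2 kit, which does not mark strand. The LPS dose and the length of treatment are not given in the sources used here.

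The authors deposited a table of read counts per gene, with 23420 features and 1 column per library, which held whole numbers that were not normalized. The submitters' processing notes name TopHat2 2.0.8, featureCounts, Subread 1.4.3, edgeR 3.6.8 and the mouse build mm10, without saying what each did. How reads that match more than 1 gene were counted is not given in the sources used here, so near-identical genes such as Lyz1 and Lyz2 or Hspa1a and Hspa1b are uncertain. No feature was blank or a total. Of the features, 21571 matched a current mouse gene symbol, 1689 an older symbol and 160 neither, and gene names are printed as the authors gave them. Coordinates come from the RefSeq annotation of GRCm38, the assembly of mm10.

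Groups and replicate numbers were taken from the sample titles. Total counts were 12243848 and 10174720 for the KO steady-state libraries 1 and 2, 9855387 and 12536554 for WT steady state, 8889752 and 8005151 for KO with LPS, and 8488443 and 15495249 for WT with LPS. Libraries of a group correlated over log2 CPM with Pearson's r of 0.981 for KO steady state, 0.972 for WT steady state, 0.954 for KO with LPS and 0.910 for WT with LPS. A chi-square statistic of their counts was 19.5, 46.7, 78.6 and 196 per gene, so no pair of libraries agreed within sampling noise. The median SD of log2 CPM within a group was 0.111, 0.196, 0.355 and 0.463.

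Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a minimum total count of 15), which left 12442. Library sizes were scaled with TMM factors, and CPM values use the scaled sizes, except those of Gata1, which use total counts. The edgeR quasi-likelihood F test was run with 1 coefficient per group over all 8 libraries, because 2 libraries against 2 alone leave few residual degrees of freedom. The fit had 4 residual and 3.40 prior degrees of freedom and a biological coefficient of variation of 0.340. The 5 comparisons were KO against WT at each treatment, LPS against steady state in each genotype, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. The SE of a log2 fold change is its size divided by the square root of F.

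Of 36 gene lists fixed beforehand, those with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. The test was repeated with a correlation estimated per list and with fry. No list was called in any of the 5 comparisons with an estimated correlation. That test rests on the 4 residual degrees of freedom of the fit, far fewer than the preset test uses. Lists with an estimated correlation under the preset 0.01 lost their calls too. For stem and progenitor markers in KO against WT with LPS (estimated correlation 0.00061) the camera p went from 3.7e-06 to 0.0087. A call lost this way therefore does not show that the members of a list vary together. Counts of called members are given over all genes tested and adjusted over the list alone.

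The design, the tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule gave (a) Gata1, St8sia4, St8sia1, St8sia2, Ncam1, Nrp2, Ccr7 and Ccl21a. It gave (b) the 10 highest and 10 lowest log2 fold changes (6 and 6 in the interaction) among called genes with a mean log2 CPM of at least 3. In a pairwise comparison these also had no overlap between the libraries of the groups, and symbols of the forms Gm with digits or Rik were left out. It gave (c) up to 4 members with the smallest adjusted p and up to 2 with the largest mean CPM of each list described. Some genes that the rule gave are not reported here. Other genes are named only where a count of 5 or fewer is spelled out or where the text says that they were chosen after their values were seen.

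The alternatives were RLE or upper-quartile factors, no filter or a stricter filter (CPM of at least 1 in 2 libraries), DESeq2 1.42.0, robust dispersion, only the groups compared, the replicate number as a block, an adjusted p under 0.01, a minimum fold of 1.5 and leaving out each library in turn. When a library is left out its group has 1 library, which is assumed to vary like the other groups. The fit then also has fewer residual degrees of freedom. A call can therefore be lost without a library that is not part of the comparison, with little change in the fold.

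The procedure was tested on simulated counts with the means and sizes of these libraries and 12239 genes passing the filter. For KO against WT with LPS it recovered 46% of 100 genes changed 4-fold and 90% of 100 changed 16-fold, and called 7 of 12016 unchanged genes. Camera called a simulated list moved 2-fold and did not call an unchanged one. The simulated genes varied independently, with the same spread in each group and no LPS response. The simulation therefore could not test false calls of lists whose members vary together, or of genes whose spread differs between groups.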

Results

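The data were RNA-seq libraries of mouse dendritic cells, which present antigen to T cells and travel from tissue to lymph nodes. The cells carried a Gata1 knock-out (KO) or were wild type (WT). Gata1 encodes a transcription factor of the erythroid, megakaryocyte, mast cell and eosinophil lineages. Cells were left at steady state or treated with LPS, a bacterial lipopolysaccharide sensed by toll-like receptor 4. Each of the 4 groups had 2 libraries, and total counts ran from 8005151 to 15495249 per library. The labels do not say whether the libraries of a group came from separate animals or cultures. The p-values thus measure a spread between libraries that may be technical. That spread was estimated over all 8 libraries together, although the groups differed in it. The median SD of log2 CPM was 0.111 in KO and 0.196 in WT at steady state, and 0.355 and 0.463 with LPS. The p-values of a comparison therefore do not measure the spread of its own libraries alone. The series title names GATA1, the chemokine CCL21 and polysialic acid, so genes of that pathway are given in each comparison. Values are counts scaled to library size (CPM) as mean ± SD over 2 libraries, and fold changes are log2 ± SE. Adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12442 genes.

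Gata1 (mm10 chromosome X, 7959260 to 7976663) had 0 reads in all 4 KO libraries. The WT steady-state libraries had 1 and 10 reads, and the WT LPS libraries had 0 and 1. Over the group, WT steady-state cells reached 0.491 CPM. A count of 0 in the KO steady-state group allows up to 0.134 CPM (3 reads over the group's total). The measured WT level was 3.67 times that floor. This ratio makes no allowance for counting error in the 11 WT reads, so it is not a lower bound on the difference. It rests on WT replicate 2, which held 10 of the 11 reads. Without that library the WT level was 0.101 CPM, under the floor, and no difference was shown. The same library held more of the basophil and mast cell genes Prss34 (55.9 against 1.35 CPM in WT replicate 1) and Cpa3 (16.7 against 0.869), both named after their values were seen. With LPS both genotypes lay at or under that floor, and no difference was detectable at this depth. Gata1 did not pass the filter on low counts. In the fit with no filter its steady-state difference had an unadjusted edgeR p of 0.0356 and an adjusted p of 1. The floors cover counting error only.

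**Figure D1:**
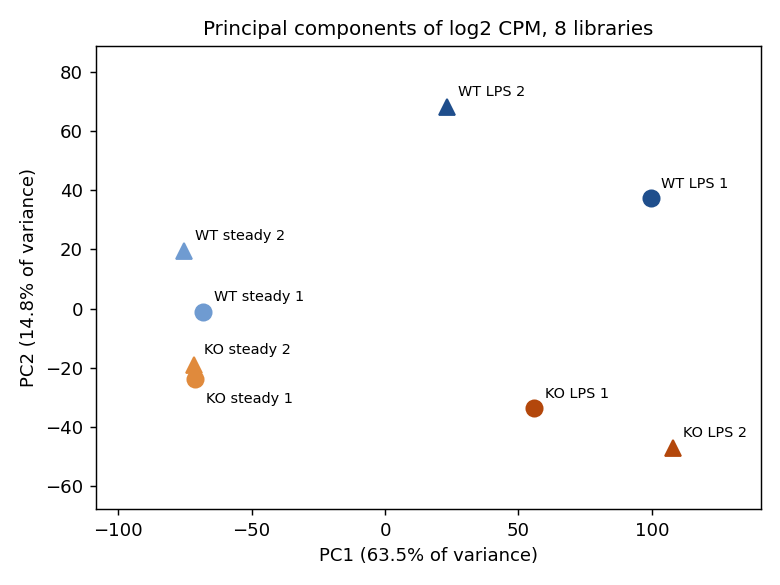
Each point is a library, placed by the first (x axis, 63.5% of variance) and second (y axis, 14.8%) principal component of log2 CPM over 12442 genes; circles are replicate 1 and triangles replicate 2. Steady-state libraries lie left and LPS libraries right, and both KO LPS libraries lie below both WT LPS libraries on the second component.

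The first comparison asked what loss of Gata1 changes in unstimulated cells. St8sia4, the enzyme that makes polysialic acid in immune cells, was at 208 ± 8.93 CPM in KO and 226 ± 51.1 in WT (log2 difference -0.12 ± 0.58, edgeR adjusted p = 1). Ccr7, the receptor for CCL21, was at 2019 ± 148 and 2957 ± 352 CPM (edgeR adjusted p = 1). Nrp2, a carrier of polysialic acid on dendritic cells, was at 339 ± 94.9 and 260 ± 41.0 CPM (edgeR adjusted p = 1). No gene passed edgeR's adjusted threshold of 0.05, against 327 genes at an unadjusted p under 0.05 and 27 genes called by DESeq2. The smallest adjusted p was 0.0726, and the histidine ammonia-lyase gene Hal, named after its values were seen, passed without WT LPS replicate 1 or 2 (adjusted p = 0.0479 and 0.0483). The libraries of the groups did not overlap in 5655 of 12442 genes (45.5%), where chance gives 33.3%. Leaving out WT replicate 2 turned the St8sia4 difference to 0.12.

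The neutrophil marker list was the lowest of the fixed lists in KO. None of its 16 tested members passed over all genes, and 7 were lower when adjusted over the list alone (camera adjusted p = 5.9e-18; adjusted p = 0.200 with an estimated correlation). S100a8 and S100a9, subunits of the calprotectin complex, were at 2.48 and 2.66, and at 2.40 and 0.974 CPM in the KO libraries. In WT replicate 1 they were at 8.60 and 9.37 CPM, and in WT replicate 2 at 50.3 and 87.9. The same WT library also held the highest B cell list level of all 8 libraries, 0.92 log2 units above the WT steady-state mean, and the highest mast cell and basophil level, 0.56 above it. Of the 7 eosinophil markers, 2 were higher in KO when adjusted over the list alone and 0 over all genes (camera adjusted p = 8.7e-05; adjusted p = 0.200 with an estimated correlation). Its call was lost without KO steady-state replicate 1 (adjusted p = 0.153) and without WT steady-state replicate 1 (adjusted p = 0.116). Among these genes Alox15, a lipoxygenase, was at 19.2 and 27.6 CPM in KO and 5.22 and 5.58 in WT. The sialic acid pathway list had 0 of 19 members past either adjustment (camera adjusted p = 0.732).

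Camera called 9 other lists at steady state, in which 0 members passed edgeR's threshold over all genes (327 genes in all at an unadjusted p under 0.05) or when adjusted over the list alone. Lower in KO were the NF-kB pathway (camera adjusted p = 8.7e-05), dendritic cell maturation (0.00116), MHC class I presentation (0.00116), stromal and endothelial markers (0.0156) and interferon-stimulated genes (0.0207). Higher were the GATA family and partners (camera adjusted p = 0.00116), cell cycle (0.00216), cholesterol biosynthesis (0.0207) and glycolysis (0.0207). With an estimated correlation their adjusted p was between 0.200 and 0.755. Without WT steady-state replicate 2 the NF-kB (camera adjusted p = 0.0647), maturation (0.178), stromal (0.148), cholesterol (0.592) and glycolysis (0.522) lists lost their calls. Without KO steady-state replicate 1 the interferon (0.653), cholesterol (0.126) and glycolysis (0.525) lists lost theirs and the stromal list turned direction (0.778). The cell cycle list lost its call without WT steady-state replicate 1 (0.269) and turned direction without KO steady-state replicate 2 (0.602), and the interferon list turned direction without WT steady-state replicate 1 (0.626).

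With LPS the genotypes differed in 96 genes, 35 higher and 61 lower in KO. With the replicate number as a block the count was 8. Same-numbered LPS libraries of the 2 genotypes deviated in opposite directions (correlation -0.599). With the numbers of the KO LPS libraries crossed, a block chosen after seeing the data, the count was 273. Cd86, Ccl17, Ccr7, Il15 and Il6 were among the genes lower in KO. The costimulatory receptor ligand Cd86 (chromosome 16, 36568956 to 36666158) was at 71.8 ± 9.96 CPM in KO and 559 ± 55.1 in WT (log2 -2.96 ± 0.26, edgeR adjusted p = 0.0138). The chemokine gene Ccl17 was at 31.2 ± 8.42 against 381 ± 268 CPM (log2 -3.61 ± 0.54, edgeR adjusted p = 0.0412). Ccr7 (chromosome 11, 99144199 to 99155077) was at 132 ± 37.3 against 795 ± 278 CPM (log2 -2.59 ± 0.40, edgeR adjusted p = 0.0439). The cytokine genes Il15 and Il6 were lower by log2 -1.89 ± 0.25 and -3.11 ± 0.40 (edgeR adjusted p = 0.0366 and 0.0344). In the dendritic cell maturation list, 4 of 29 tested members were lower and 0 higher, or 18 lower when adjusted over the list alone. Its camera adjusted p was 1.1e-13, and the adjusted p was 0.194 with an estimated correlation. Lists of cell type markers were also called by camera, some lower and some higher in KO. The identity, stem and progenitor, and mast cell and basophil lists share members, so their calls are not independent results. Of 15 dendritic cell identity markers 1, Ccr7, was lower and 0 higher, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.00109; adjusted p = 0.194 with an estimated correlation). Of 9 stem and progenitor markers 1, Slamf1, was lower and 0 higher, or 4 lower when adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.194 with an estimated correlation). Of 9 mast cell and basophil markers 0 were called, with 3 lower when adjusted over the list alone, and the list was lower (camera adjusted p = 0.0177; adjusted p = 0.219 with an estimated correlation). Of 14 megakaryocyte and platelet markers 0 were called, with 1 higher when adjusted over the list alone, and the list was higher (camera adjusted p = 0.0177; adjusted p = 0.219 with an estimated correlation). The mast cell and basophil list lost its call without KO LPS replicate 1 or WT LPS replicate 2 (camera adjusted p = 0.138 and 0.0574), and the megakaryocyte and platelet list without KO LPS replicate 1, WT LPS replicate 1 or WT LPS replicate 2 (0.116, 0.149 and 0.0536). The count of 96 fell to 1 without either KO LPS library, to 3 without either KO steady-state library and to 9 without either WT steady-state library. It rose to 826 without WT LPS replicate 1 and to 206 without WT LPS replicate 2, was 0 with edgeR on only these 4 libraries (2108 genes at an unadjusted p under 0.05 in the fit to all 8), and was 1062 with DESeq2, which called all 96. Without any 1 of the 4 KO or 2 WT steady-state libraries the calls of Cd86, Ccl17, Ccr7 and Il15 were lost, and that of Il6 without any 1 of the 4 KO libraries. The steady-state libraries enter this comparison only through the shared spread, filter and scaling. With a library left out the log2 differences kept their direction. They ranged from -3.11 to -2.84 for Cd86, -4.18 to -2.62 for Ccl17, -2.91 to -2.17 for Ccr7, -2.14 to -1.71 for Il15 and -3.15 to -3.10 for Il6.

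Clec10a, Clec4a2, Clec4a3, Apoe, Lyz1, Lipa and March1 were higher in KO cells treated with LPS. The lectin receptor gene Clec10a was at 46.3 ± 13.9 CPM in KO and 1.37 ± 0.0711 in WT (log2 5.06 ± 0.64, edgeR adjusted p = 0.0342). The related lectin receptors Clec4a2 and Clec4a3 were higher by log2 2.17 ± 0.24 and 2.36 ± 0.37 (edgeR adjusted p = 0.0283 and 0.0445). Clec10a and Clec4a2 were the 2 called members among 14 type 2 and monocyte-derived dendritic cell markers, with 5 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00969; adjusted p = 0.387 with an estimated correlation). The list lost its call without KO LPS replicate 1 or WT LPS replicate 1 (camera adjusted p = 0.116 and 0.214). Apoe, which encodes a lipid-carrying apolipoprotein (chromosome 7, 19696244 to 19701310), was at 659 ± 407 against 46.7 ± 3.14 CPM (log2 3.82 ± 0.57, edgeR adjusted p = 0.0412). The lysosomal lipase gene Lipa was at 1785 ± 162 against 395 ± 15.5 CPM (edgeR adjusted p = 0.0412). Apoe and the lysozyme gene Lyz1 were the 2 called members among 23 macrophage markers, with 5 higher when adjusted over the list alone. That list had a median log2 difference of 1.53 (camera adjusted p = 1.4e-09; adjusted p = 0.219 with an estimated correlation). The near-identical Lyz2, whose reads Lyz1 can share, was at 13019.8 ± 4269.6 and 2156 ± 141 CPM (edgeR adjusted p = 0.0583). Lipa was the 1 called member of 37 lysosome and phagocytosis genes, with 2 when adjusted over the list alone (camera adjusted p = 3.2e-08; adjusted p = 0.301 with an estimated correlation). March1 (now Marchf1), an E3 ligase that removes MHC class II and CD86 from the cell surface, was higher by log2 2.09 ± 0.33 (edgeR adjusted p = 0.0445). The calls of these 7 genes were each lost without either KO library of either treatment, and all but that of Clec10a without either WT steady-state library (edgeR adjusted p = 0.0670 to 0.164). Those of Clec10a, Apoe, Lyz1 and March1 were also lost without WT LPS replicate 2 (0.0505 to 0.0645), and Lyz2 was called without WT LPS replicate 1 (0.0325).

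The highest fold in KO among the genes the naming rule allowed was that of Gdpd3, a lysophospholipase gene (chromosome 7, 126766414 to 126775645). It was at 217 ± 164 CPM in KO and 1.30 ± 0.346 in WT (log2 7.32 ± 0.84, edgeR adjusted p = 0.0283), and at 112 ± 73.1 and 4.73 ± 0.691 CPM at steady state (edgeR adjusted p = 0.399). Colec12, Pld4, Gpx3 and Rnf128 were also higher, by log2 3.47, 2.97, 2.96 and 2.43. Among the lowest were Grasp (now Tamalin) at -4.12, the semaphorin gene Sema7a at -4.07, Slamf1 at -3.87, Hip1r at -3.75, Tspan13 at -3.70 and the decoy interleukin-1 receptor gene Il1r2 at -3.23. All 96 called genes had both KO libraries on the same side of both WT libraries, as did 4490 of 12442 genes (36.1%), where chance gives 33.3%. Tspan13 lost its call without either KO LPS library, Colec12 and Grasp without either KO library of either treatment, and the other 8 also without either WT steady-state library (edgeR adjusted p = 0.0587 to 0.166).

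St8sia4 (chromosome 1, 95587682 to 95667717) was at 287 and 134 CPM in the KO LPS libraries and 138 and 460.3 in the WT LPS libraries. The difference of log2 -0.51 ± 0.58 was smaller than the spread within the groups (edgeR adjusted p = 0.732), and leaving out WT LPS replicate 2 turned it to 0.62. Nrp2 was at 675 ± 74.0 in KO and 235 ± 169 CPM in WT (edgeR adjusted p = 0.198). Of 19 sialic acid pathway genes the 1 called was Npl, which breaks down free sialic acid, at 29.5 ± 5.09 against 6.56 ± 0.263 CPM (edgeR adjusted p = 0.0411). Npl kept its call without WT LPS replicate 1 and lost it without each of the other 7 libraries (edgeR adjusted p = 0.0540 to 0.153), and Nrp2 was called without WT LPS replicate 2 (0.0356). The polysialyltransferase gene St8sia2 and the carrier gene Ncam1 had at most 8 reads in any library, and Ccl21a had 0 reads in all 8.

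The interferon-stimulated genes were not called between genotypes with LPS, with 0 of 43 members higher and 0 lower, or 2 lower when adjusted over the list alone (camera adjusted p = 0.161, or 0.0126 without KO LPS replicate 1 and 0.0146 without WT LPS replicate 1). Il6 was the 1 called of 22 LPS-induced cytokines and mediators. That list was lower by camera (adjusted p = 0.00345; adjusted p = 0.387 with an estimated correlation), with 5 lower and 1 higher when adjusted over the list alone. Its call was lost without KO LPS replicate 1 (0.0503) or WT LPS replicate 1 (0.154), and that of Il6 without either KO library of either treatment (edgeR adjusted p = 0.124 to 0.152). The NF-kB pathway list had 0 members called over all genes, and 9 lower and 1 higher of 28 when adjusted over the list alone (camera adjusted p = 0.000177; adjusted p = 0.219 with an estimated correlation). Camera also called the glycolysis list higher (adjusted p = 0.00128) and the chemokine (0.00691) and cholesterol biosynthesis (0.0304) lists lower. With an estimated correlation each had an adjusted p of 0.387. Over all genes 0 of 20 glycolysis genes were called, and 1 of 22 chemokines and 1 of 24 cholesterol genes were lower. Adjusted over the list alone, 0 glycolysis genes passed, 6 chemokines were lower, and 3 cholesterol genes were lower and 1 higher. The libraries of the LPS groups lay apart. Hspa1a, a heat shock gene whose reads Hspa1b can share, was at 273 CPM in WT LPS replicate 1 and at 9.28, 5.42 and 20.8 in WT replicate 2 and the KO LPS libraries.

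**Figure D2:**
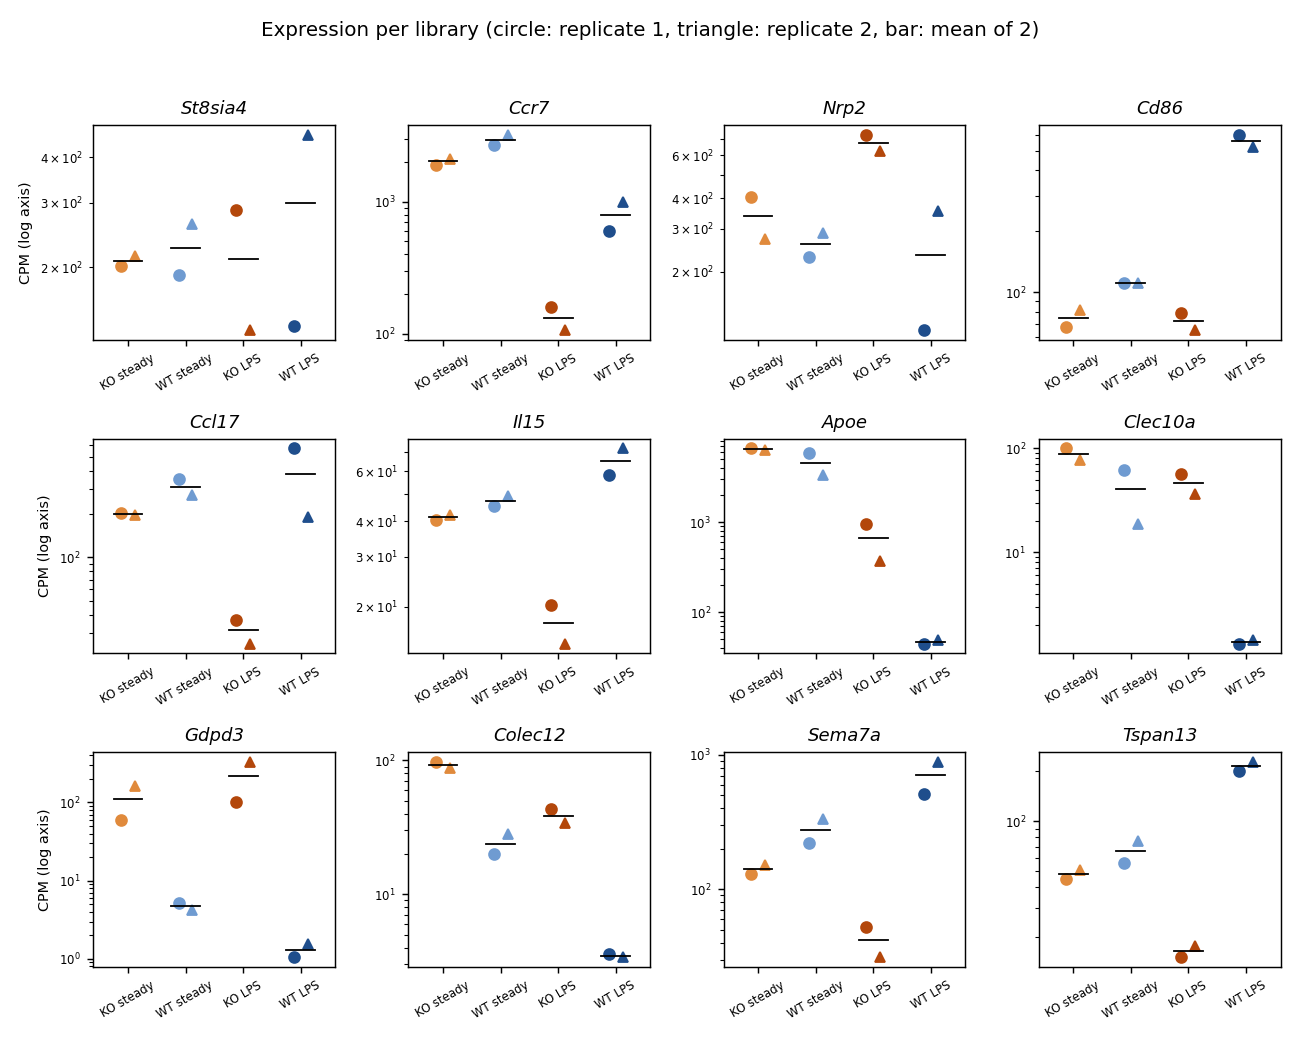
CPM (y axes, log scale) of 12 genes in each library, by group on the x axis; circles are replicate 1, triangles replicate 2 and bars the mean of 2. Cd86 lay at 78.8 and 64.8 CPM in the KO LPS libraries and at 598 and 520 in the WT LPS libraries, while the St8sia4 points of the LPS groups overlap.

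LPS changed 807 genes in WT cells, 373 upwards and 434 downwards. Nos2, the inducible nitric oxide synthase, went from 0.342 ± 0.0629 to 971 ± 805 CPM (log2 11.44 ± 1.24, edgeR adjusted p = 0.00516). Ptgs2, the inducible cyclooxygenase, went from 0.911 ± 0.605 to 622 ± 491 CPM (log2 9.35 ± 1.16, edgeR adjusted p = 0.00749). Il1b, Irg1 (now Acod1, the itaconate-making enzyme) and the acute-phase gene Saa3 rose by log2 5.08, 6.76 and 7.02. Of 22 LPS-induced cytokines and mediators 16 rose and 0 fell, with 21 higher when adjusted over the list alone (camera adjusted p = 1.6e-32; adjusted p = 0.130 with an estimated correlation). Of 43 interferon-stimulated genes 25 rose and 0 fell, with 35 higher when adjusted over the list alone (camera adjusted p = 4.7e-35; adjusted p = 0.230 with an estimated correlation). They included Oasl1 at log2 6.08 ± 0.39, Isg15 at 6.0 ± 0.55, Rsad2 at 6.40 ± 0.62 and Irf7, the master regulator of type I interferon genes, at 6.04 ± 0.59. In the MHC class I list 4 of 17 members rose, among them the peptide transporter gene Tap1 (log2 1.70) and H2-K1 (log2 1.73), whose reads other class I genes can share. The list had a camera adjusted p of 3.5e-05, and an adjusted p of 0.315 with an estimated correlation, and 9 members were higher when adjusted over the list alone. Without WT steady-state replicate 1 or 2 the calls of Nos2, Ptgs2, Saa3, Tap1 and H2-K1 were lost, and without replicate 1 that of Rsad2 (edgeR adjusted p = 0.0543 to 0.256). H2-K1 also lost its call without either KO steady-state library, KO LPS replicate 1 or WT LPS replicate 1 (0.0534 to 0.113).

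The levels of the macrophage and monocyte-derived dendritic cell marker lists fell with LPS in both genotypes. In KO cells Mrc1, Apoe and Ccr2 changed by log2 -6.00, -3.29 and -7.05. In WT cells the mannose receptor gene Mrc1 fell from 209.6 ± 21.5 to 0.901 ± 1.09 CPM (edgeR adjusted p = 0.0140), Apoe from 4547 ± 1738 to 46.7 ± 3.14 (edgeR adjusted p = 0.00454) and the chemokine receptor gene Ccr2 from 481 ± 222 to 1.12 ± 0.0832 (edgeR adjusted p = 0.00441). The complement gene C1qa changed by log2 -4.74 and the transcription factor gene Spib by -5.56. Of 23 macrophage markers 9 fell and 1 rose, with 12 lower and 2 higher when adjusted over the list alone (camera adjusted p = 4.4e-07; adjusted p = 0.315 with an estimated correlation). Of 14 type 2 and monocyte-derived dendritic cell markers 6 fell and 0 rose, among them the lectin genes Mgl2 (log2 -4.98) and Clec10a (log2 -4.85), with 7 lower when adjusted over the list alone (camera adjusted p = 1.3e-07; adjusted p = 0.230 with an estimated correlation). Mrc1 and Spib lost their calls without WT steady-state replicate 1 or 2, and C1qa without replicate 1 (edgeR adjusted p = 0.0578 to 0.0848).

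Maturation genes went both ways in WT cells. Cd86 rose from 111 ± 0.460 to 559 ± 55.1 CPM (edgeR adjusted p = 0.00542), Il12b, a subunit of interleukin-12, from 122 ± 84.6 to 844 ± 18.6 (edgeR adjusted p = 0.0210) and the cytokine-signalling inhibitor gene Socs3 by log2 3.52. Ccr7 fell from 2957 ± 352 to 795 ± 278 CPM (log2 -1.89 ± 0.39, edgeR adjusted p = 0.0340). In all, 6 of 29 maturation genes rose and 2 fell, with 10 and 5 when adjusted over the list alone (camera adjusted p = 0.104). Among chemokines 6 of 22 rose, including Cxcl3 (log2 5.66) and Ccl5 (log2 2.72), and 2 fell, including Ccl6 (log2 -2.97), with 10 and 2 when adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.349 with an estimated correlation). In the migration list 7 of 44 genes fell and 0 rose, among them Ccr2, Ccr7 and the elastase gene Mmp12 (log2 -2.53), with 10 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00349; adjusted p = 0.349 with an estimated correlation). The level of this list (mean log2 CPM minus the WT steady-state mean) also fell in KO, from 0.0059 and 0.041 to -0.73 and -1.13. In WT St8sia4 was at 226 ± 51.1 and 299 ± 228 CPM (edgeR adjusted p = 0.678), and the sialyltransferase gene St3gal1 rose by log2 1.37 ± 0.28 (edgeR adjusted p = 0.0343). Of 19 sialic acid pathway genes 1 rose and 3 fell, with 1 and 4 when adjusted over the list alone (camera adjusted p = 0.104, and 0.0258 downwards with fry's directional test). Those that fell were Npl (log2 -1.50), Slc17a5 (-1.20) and St8sia1 (-3.12), and each lost its call when some single libraries were left out. Ccr7 lost its call without any 1 of the 4 steady-state libraries or WT LPS replicate 1 (edgeR adjusted p = 0.0708 to 0.177). Cd86 and Cxcl3 lost theirs without either WT steady-state library, Ccl5, Ccl6 and Mmp12 without any 1 of the steady-state libraries, St3gal1 also without KO LPS replicate 1, and Il12b without replicate 1 of either steady-state group (edgeR adjusted p = 0.0502 to 0.253). Without WT LPS replicate 1 the migration list had a camera adjusted p of 0.0557 and the maturation list of 0.0122, and without WT LPS replicate 2 the St8sia4 difference was -0.71. The count of 807 was 70 without WT steady-state replicate 1, 119 without replicate 2, 370 and 378 without the KO steady-state libraries and 3629 without WT LPS replicate 2. It was 229 with only the WT libraries and 1995 with DESeq2, which called all 807.

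LPS changed 1463 genes in KO cells, 659 upwards and 804 downwards. Saa3 went from 9.48 ± 2.00 to 6847 ± 4629.5 CPM (log2 9.50 ± 0.88, edgeR adjusted p = 0.00297) and the iron-binding lipocalin gene Lcn2 from 2.95 ± 1.21 to 2418 ± 482 (log2 9.68 ± 1.33, edgeR adjusted p = 0.00810). The scavenger receptor gene Marco rose from 0.559 ± 0.462 to 244 ± 3.25 CPM (edgeR adjusted p = 0.00554), and Susd2 from 0.465 ± 0.219 to 316 ± 22.1 (edgeR adjusted p = 0.00133). Lcn2 was 1 of 6 members that rose among 16 tested neutrophil markers, with 0 that fell, or 7 and 1 when adjusted over the list alone (camera adjusted p = 3.6e-05; adjusted p = 0.297 with an estimated correlation). The others were Ly6i, whose reads other Ly6 genes can share, 1100001G20Rik (log2 4.82 ± 0.52, edgeR adjusted p = 0.00411), Chi3l1 (log2 5.35 ± 0.89, edgeR adjusted p = 0.0145), Camp and Stfa3. In WT 2 of the 16, Ly6i and Lcn2, rose and 2, Cxcr2 and Mmp8, fell, or 5 and 8 when adjusted over the list alone. The genotypes lay farther apart in this list at steady state than with LPS. Its level (mean log2 CPM minus the WT steady-state mean) was -1.93 and -1.80 in KO and -0.86 and 0.86 in WT at steady state. With LPS it was 0.24 and 0.44 in KO and 0.15 and -0.14 in WT. The WT list had a median log2 change of -1.50 and was not called (camera adjusted p = 0.703 upwards; adjusted p = 0.845 with an estimated correlation), but was called downwards without WT steady-state replicate 1 (camera adjusted p = 0.0308). Of 43 interferon-stimulated genes 28 rose and 0 fell, including Irf7 (log2 6.80) and Bst2 (log2 3.48), with 34 higher when adjusted over the list alone (camera adjusted p = 1.3e-28; adjusted p = 0.218 with an estimated correlation). Of 22 LPS-induced cytokines and mediators 11 rose and 0 fell, with 17 higher when adjusted over the list alone (camera adjusted p = 9.6e-18; adjusted p = 0.218 with an estimated correlation). In the MHC class I list 6 of 17 members rose (camera adjusted p = 1.5e-05; adjusted p = 0.272 with an estimated correlation), with 10 when adjusted over the list alone. Lcn2 and Bst2 lost their calls without either KO steady-state library, and Marco without replicate 1 (edgeR adjusted p = 0.0520 to 0.0796), and Chi3l1 without either KO steady-state library or KO LPS replicate 2 (0.0678 to 0.102).

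Dendritic cell identity genes fell in KO cells with LPS. Their list level (mean log2 CPM minus the WT steady-state mean) also fell in WT, from 0.041 and -0.041 to -1.14 and -0.52. In KO it went from -0.028 and 0.013 to -1.80 and -1.94. Ccr7 went from 2019 ± 148 to 132 ± 37.3 CPM (log2 -3.93 ± 0.42, edgeR adjusted p = 0.00417). The transcription factor gene Zbtb46, a marker of conventional dendritic cells, went from 61.7 ± 9.13 to 8.44 ± 5.0 CPM (edgeR adjusted p = 0.0143), and Flt3, the receptor of their growth factor, from 34.3 ± 1.22 to 0.379 ± 0.103 (edgeR adjusted p = 0.0324). Of 15 identity markers 6 fell and 1 rose, with 8 and 2 when adjusted over the list alone (camera adjusted p = 0.000210; adjusted p = 0.218 with an estimated correlation). Of 29 maturation genes 6 fell, including Ccl17 (log2 -2.68), and 4 rose, including Socs3 (log2 3.47), with 15 and 4 when adjusted over the list alone (camera adjusted p = 0.0450; adjusted p = 0.534 with an estimated correlation). Ciita, the activator of MHC class II genes, changed by log2 -2.96 ± 0.60 (edgeR adjusted p = 0.0257). Other members of the MHC class II presentation list went both ways, with H2-DMb2 at log2 -2.14 and March1 at 1.64. The level of that list went from -0.23 and -0.11 to -1.05 and -0.66 in KO, and from 0.32 and -0.32 to -0.22 and -0.53 in WT. Zbtb46 lost its call without either KO steady-state library or KO LPS replicate 2 (edgeR adjusted p = 0.0613 to 0.0838). Flt3, Ccl17 and Ciita lost theirs without any 1 of the KO or WT steady-state or KO LPS libraries (edgeR adjusted p = 0.0520 to 0.192). The maturation list lost its call without KO LPS replicate 2 (camera adjusted p = 0.186).

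Cell cycle and sterol genes fell and glycolytic genes rose in KO cells, and the levels of these lists moved the same way in WT cells. In the cell cycle list 11 of 34 genes fell and 0 rose, among them the replication helicase genes Mcm5 (log2 -3.34) and Mcm3 (log2 -1.68), with 25 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.0e-07; adjusted p = 0.398 with an estimated correlation). In the cholesterol biosynthesis list 7 of 24 fell, with 9 when adjusted over the list alone (camera adjusted p = 0.000141; adjusted p = 0.218 with an estimated correlation). In the glycolysis list 6 of 20 rose and 0 fell, including Hk2 (log2 1.77) and the glucose transporter gene Slc2a1 (log2 2.64), with 14 when adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.297 with an estimated correlation). In WT cells 3 of 34 cell cycle genes fell and 0 rose, with 12 lower when adjusted over the list alone (camera adjusted p = 0.00262; adjusted p = 0.576 with an estimated correlation). They were Cenpf and Ccnb2, at 2.99 and 5.58 and at 2.41 and 3.94 CPM at steady state and at most 0.186 with LPS, and the cyclin gene Ccnd1 (log2 -2.44). The 1 of 20 glycolysis genes that rose in WT was Hk2 (log2 1.30), with 3 higher when adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.357 with an estimated correlation). The cholesterol list in WT went from levels of 0.11 and -0.11 at steady state to -0.20 and -0.58 with LPS. In the interaction the glycolysis list had a camera adjusted p of 0.0513, and it was called without replicate 1 of KO steady state, KO LPS or WT LPS (0.00915, 0.0362 and 0.000488) or WT steady-state replicate 2 (0.0195). Each of the 4 WT gene calls was lost without either WT steady-state library, either KO LPS library or WT LPS replicate 1, those of Cenpf, Ccnb2 and Hk2 without KO steady-state replicate 2, and that of Hk2 without KO steady-state replicate 1 (edgeR adjusted p = 0.0517 to 0.240). The WT cell cycle list lost its call without WT steady-state replicate 2 (camera adjusted p = 0.0511) or WT LPS replicate 2 (0.255). St8sia4 was at 208 ± 8.93 and 211 ± 108 CPM (edgeR adjusted p = 0.985). The ganglioside sialyltransferase gene St8sia1 had 58 and 33 reads in the KO steady-state libraries and 1 in each KO LPS library (edgeR adjusted p = 0.0182). It also fell in WT, from 16 and 46 reads to 1 and 6 (log2 -3.12). Mcm5 lost its call without replicate 2 of either KO group, Mcm3 and St8sia1 without any 1 of the 4 KO libraries, Hk2 without either KO steady-state library or KO LPS replicate 2, and Slc2a1 without any 1 of the 4 KO libraries or either WT steady-state library (edgeR adjusted p = 0.0507 to 0.201). The St8sia4 difference of log2 0.02 became -0.02 without KO steady-state replicate 1 and -0.63 without KO LPS replicate 1. The count of 1463 was 144 and 143 without KO steady-state replicate 1 or 2, 884 and 249 without KO LPS replicate 1 or 2, 611 and 634 without the WT steady-state libraries, and 3345 and 3328 without the WT LPS libraries. It was 2316 with only the KO libraries and 2846 with DESeq2, which called 1461 of the 1463.

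**Figure D3:**
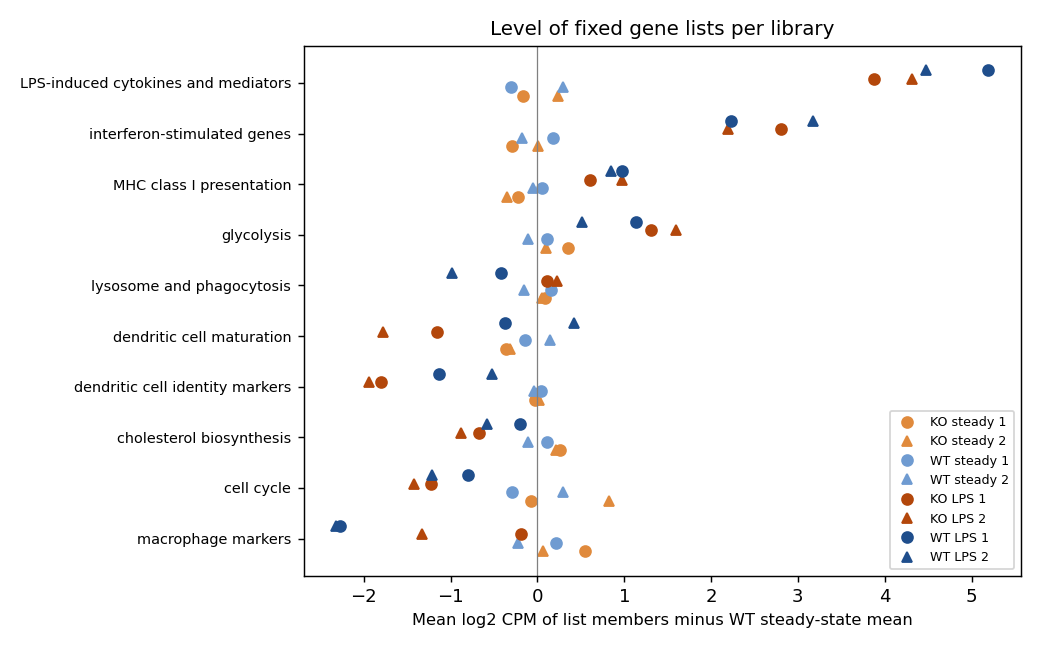
Level of 10 fixed gene lists (y axis) in each library, as the mean log2 CPM of the tested members minus the mean of the WT steady-state libraries (x axis); circles are replicate 1 and triangles replicate 2. Macrophage markers lay at -0.19 and -1.33 in the KO LPS libraries and at -2.27 and -2.31 in the WT LPS libraries, and dendritic cell maturation genes at -1.15 and -1.78 against -0.37 and 0.42.

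The LPS responses of the genotypes ran alike across genes. Of the genes LPS raised, 265 were called in both genotypes, where independent lists of those sizes would share 19.8, and of those it lowered 287, where they would share 28.0. The calls went in opposite directions for 1 gene. The log2 changes correlated across 12442 genes, which are not independent replicates, with Pearson's r of 0.794 and Spearman's rho of 0.758. The genotype differences at steady state and with LPS correlated less, with Pearson's r of 0.415 and Spearman's rho of 0.362. Of the 96 genes called with LPS, 88 had the same sign at steady state. Leaving out WT steady-state replicate 2 lowered the r of the genotype differences to 0.218 and leaving out WT LPS replicate 2 to 0.245, and over the other libraries left out in turn it lay between 0.319 and 0.418. Leaving out WT LPS replicate 1 lowered the r of the LPS responses to 0.675.

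The difference between the genotypes' LPS responses was tested as an interaction. Cd86 had an interaction of log2 -2.39 ± 0.35 (edgeR adjusted p = 0.416), Ccr7 of -2.04 ± 0.54 (edgeR adjusted p = 0.579) and Apoe of 3.32 ± 0.74 (edgeR adjusted p = 0.532). No gene passed edgeR's adjusted threshold, against 797 at an unadjusted p under 0.05 and 113 called by DESeq2, and the smallest edgeR adjusted p was 0.337. DESeq2 called the interactions of Cd86 (adjusted p = 2.0e-07), Apoe (0.000697) and Ccr7 (0.0127), and the adjusted p of each reached 1 among the other alternatives.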

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

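The tests of a weaker LPS response and of the macrophage share were chosen only after the result was seen.

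A total of 13 gene lists differed between the LPS responses of the genotypes by the camera test of the interaction, while no single gene did with edgeR (797 at an unadjusted p under 0.05, 113 called by DESeq2). With an estimated correlation their adjusted p lay between 0.166 and 0.557, so each of the 13 calls was lost. Lower in the KO response were dendritic cell maturation (camera adjusted p = 4.2e-10), LPS-induced cytokines and mediators (0.000623), cell cycle (0.000623), cholesterol biosynthesis (9.9e-05), dendritic cell identity markers (0.000339), mast cell and basophil markers (0.00678) and stem and progenitor markers (2.3e-06). The chemokine list was also called lower (camera adjusted p = 0.0429), with a median interaction of log2 -0.09. Higher in the KO response were lysosome and phagocytosis genes (camera adjusted p = 2.2e-07), macrophage markers (1.1e-08), neutrophil markers (1.6e-11), megakaryocyte and platelet markers (0.00633) and type 2 and monocyte-derived dendritic cell markers (0.0131). The macrophage and type 2 lists fell with LPS in both genotypes. As list levels (mean log2 CPM minus the WT steady-state mean), macrophage markers went from 0.55 and 0.059 to -0.19 and -1.33 in KO. With LPS in WT they were at -2.27 and -2.31. The type 2 list went from -0.11 and 0.19 to -1.51 and -2.12 in KO, and was at -2.58 and -2.04 with LPS in WT.

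Leaving out 1 library ended several of these calls. Without WT LPS replicate 1, 8 lists were called, and the lists of cytokines (0.0833), chemokines (0.378), cell cycle (0.147), cholesterol biosynthesis (0.0833), type 2 and monocyte-derived dendritic cells (0.289), mast cells and basophils (0.144) and megakaryocytes (0.0672) lost their calls, with the camera adjusted p in brackets. Without KO LPS replicate 1 the lists of chemokines (0.454), type 2 and monocyte-derived dendritic cells (0.292), mast cells and basophils (0.292) and megakaryocytes (0.0871) lost theirs. Without KO steady-state replicate 2 those of chemokines (0.643), cell cycle (0.267) and mast cells and basophils (0.176) did. Without KO steady-state replicate 1 the lists of type 2 and monocyte-derived dendritic cells (0.0790) and mast cells and basophils (0.0723) did, and without WT steady-state replicate 2 those of chemokines (0.164) and megakaryocytes (0.0942). The mast cell and basophil list also lost its call without WT steady-state replicate 1 (0.382) or WT LPS replicate 2 (0.110).

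The neutrophil list kept its call without any 1 of the 8 libraries (camera adjusted p at most 2.1e-05), and the mast cell and basophil list without WT steady-state replicate 2 (0.0111). WT steady-state replicate 2 held S100a9 at 87.9 CPM, against at most 9.37 in the other 7 libraries, and the basophil protease gene Prss34 at 55.9 CPM, against at most 1.35. Prss34 was chosen after its values were seen. The neutrophil list level was already lower in KO at steady state (-1.93 and -1.80, against -0.86 and 0.86 in WT). With LPS it was at 0.24 and 0.44 in KO and 0.15 and -0.14 in WT.

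As lists, maturation genes were lower and macrophage markers higher in the KO LPS libraries than in the WT LPS libraries. Over all genes 4 of 29 maturation genes and 2 of 23 macrophage markers were called. Both camera calls were lost with an estimated correlation (adjusted p = 0.194 and 0.219). A weaker LPS response of the KO cells as a whole cannot be told apart from a change in these genes alone: the 25 interferon-stimulated genes called higher with LPS in WT had a median difference in log2 response of 0.196 (95% bootstrap interval over genes -0.22 to 0.41), and over pairs of 1 KO and 1 WT LPS library this median ran from -0.18 to 0.41 but the mean of all 43 tested members from -0.83 to 0.72. The 16 LPS-induced cytokines and mediators called higher with LPS in WT had a median of -0.90 (-1.93 to -0.05). Both sets were picked by their call in WT, which favours genes whose WT rise is estimated too high and so lowers the median. Genes are not replicates, so neither interval covers the spread between libraries. The interferon-stimulated list was called lower in KO with LPS only when KO LPS replicate 1 or WT LPS replicate 1 was left out. A larger share of macrophages could account for part of the pattern and cannot be told apart from a change within the cells, since 13 of 23 tested macrophage markers (56.5%) were higher in both KO LPS libraries and 0 were lower in both. The genotype stays open as an untested biological explanation.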

How the results depend on the processing

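The crossed block, the fits without both LPS libraries numbered 2 and the Gata1 level in WT at steady state with TMM-scaled library sizes (0.462 CPM) were chosen only after the result was seen, and all other alternatives before. Over the single genes and lists tracked, 2844 values under an alternative kept their direction and side of the threshold, 720 lost a call, 57 gained one and 24 turned direction. Of the counts, correlations and levels that answer a comparison, 128 stayed within a limit and 72 did not. The limit was 1.5 times for counts and a jackknife SE, taken from the fits with each library left out, for correlations. For the Gata1 level it was the SD of the 2 WT steady-state libraries. These SE and SD limits come from the left-out libraries themselves, so staying within them says little about leaving a library out. Where a cause is not given by the construction (fewer samples, a stricter threshold), the cause was not tested.

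Counts are given in the order KO against WT at steady state, KO against WT with LPS, LPS in WT, LPS in KO and the interaction. They were 9, 538, 1497, 2223 and 3 without a filter on low counts, and 27, 1062, 1995, 2846 and 113 with DESeq2. With only the groups compared they were 1, 0, 229 and 2316. For KO against WT with LPS, LPS in WT and LPS in KO, they were 1, 150 and 219 at an adjusted p under 0.01, and 23, 502 and 805 against a minimum fold of 1.5. Without both LPS libraries numbered 2, which leaves 1 LPS library per genotype, they were 1, 2597, 5977, 2515 and 576. That fit takes its spread from the steady-state libraries alone, whose median SD over genes was 0.111 in KO and 0.196 in WT on the log2 scale, against 0.355 and 0.463 with LPS. Leaving out each library in turn gave 0 to 1, 1 to 826, 70 to 3629 and 143 to 3345 calls, and 0 in the interaction each time with edgeR (797 at an unadjusted p under 0.05 with all libraries).

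The replicate number as a block gave 8, 465 and 776 calls for KO against WT with LPS, LPS in WT and LPS in KO, and left the counts of 0 at steady state and in the interaction at 0 with edgeR. Same-numbered libraries of different groups had deviations that correlated between -0.599 (KO and WT with LPS) and 0.260 (WT steady state and WT with LPS), and with 2 numbers the pairing is not established. A block with the numbers of the KO LPS libraries crossed, chosen after seeing the data, gave 273 calls for KO against WT with LPS.

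The correlation of the LPS responses was 0.589 without a filter, 0.676 without both LPS libraries numbered 2 and 0.675 to 0.773 with each library left out. That of the genotype effects was 0.217, 0.228 and 0.218 to 0.418. The Gata1 level in WT at steady state was 0.101 to 0.798 CPM with either library left out. It rests on 11 reads, a depth at which single reads move it, and why the libraries differ was not tested.

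Of the lists, 11, 13, 13, 15 and 13 were called by camera with the preset correlation, 0 in each comparison with an estimated correlation, and 0, 24, 27, 30 and 8 by fry's mixed test. The test with an estimated correlation also has few degrees of freedom, so its lost calls need not come from correlated members. Fry's directional test called 0, 5, 14, 17 and 0, of which 0, 5, 9, 13 and 0 were also called by camera. Leaving out each library gave 8 to 16, 10 to 15, 10 to 17, 14 to 16 and 8 to 18 lists.

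Apart from 3 lists at steady state, which had been called, and the neutrophil list for LPS in WT, the values that turned direction passed the threshold neither before nor after. That neutrophil list had a camera adjusted p of 0.0308 (downwards, without WT steady-state replicate 1) to 0.935 with a library left out. St8sia4 in LPS against steady state in KO went from log2 0.02 to -0.0072 with upper-quartile factors and to between -0.63 and 0.44 with a library left out. Its other differences ranged from -0.34 to 0.12 (KO against WT at steady state), from -1.16 to 0.62 (with LPS) and from -0.71 to 1.03 (LPS in WT) with a library left out. Without both LPS libraries numbered 2 it was at 1.06 for KO against WT with LPS and -0.71 for LPS in WT, and Lyz2 for LPS in KO was at 0.034. With a library left out Nrp2 for LPS in WT ranged from -1.18 to 0.45 and Lyz2 for LPS in KO from -0.65 to 0.0083. Hspa1a for KO against WT with LPS went from -3.43 to between -4.71 and 0.48. The interferon-stimulated list had a camera adjusted p of 0.0126 to 0.822 for KO against WT with LPS and 0.0626 to 0.423 in the interaction with a library left out. For KO against WT at steady state that range was 3.7e-06 to 0.653 for the interferon-stimulated list, 1.9e-13 to 0.602 for the cell cycle list and 1.2e-14 to 0.778 for the stromal and endothelial list.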

Other observations

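The tests of mixed RNA, exchanged libraries and chromosome segments were chosen only after the result was seen, and that of depth before.

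Genes of toll-like receptor signalling changed with LPS in both genotypes. Irak3, an inhibitor of the pathway, went from 23.5 ± 0.608 to 129 ± 16.6 CPM in WT (edgeR adjusted p = 0.00464) and from 30.2 ± 0.677 to 252 ± 49.9 in KO (edgeR adjusted p = 0.00297). Cd14, a co-receptor for LPS, rose by log2 3.50 ± 0.54 in WT and 2.98 ± 0.52 in KO, and Tlr2 by 2.35 ± 0.24 and 1.23 ± 0.24. In WT 3 of 26 members rose and 1 fell, with 8 and 6 when adjusted over the list alone (camera adjusted p = 0.120). In KO 6 rose and 1 fell, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0412; adjusted p = 0.280 with an estimated correlation). Without KO steady-state replicate 1 or 2 or KO LPS replicate 1 the KO list lost its call (camera adjusted p = 0.0577, 0.0668 and 0.211), and without WT LPS replicate 1 the WT list gained one (0.0182). With edgeR, Tlr2 in KO lost its call without any of the 4 KO libraries (adjusted p = 0.0610 to 0.178), and Cd14 in KO without either KO steady-state library or KO LPS replicate 2 (0.0855 to 0.134). In WT, Irak3 and Tlr2 lost theirs without WT steady-state replicate 1 (edgeR adjusted p = 0.0594 for each), and Cd14 without either WT steady-state library (0.0852 to 0.109).

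Eosinophil markers fell with LPS, 2 of 7 in WT and 4 in KO, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.00400 and 0.000282; adjusted p = 0.315 and 0.218 with an estimated correlation). Without WT LPS replicate 2 the WT list lost its call (camera adjusted p = 0.217).

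The LPS libraries of a group lay apart, with Pearson's r of 0.910 in WT and 0.954 in KO. A difference in depth is argued against, since r in WT was 0.911 and in KO 0.955 after all libraries were thinned to 8005151 counts. RNA of unstimulated cells mixed into WT LPS replicate 2 would hold every gene above a common share of its steady-state level, but over 19 genes that fell at least 20-fold in both KO LPS libraries the 10th percentile there was 0.230%, although the median was 6.42% against 0.903% in replicate 1. An exchange of WT LPS replicate 1 with KO LPS replicate 2 is argued against: of the 20 genes that best separate the genotypes at steady state, 15 put WT LPS replicate 1 on the WT side of KO LPS replicate 2, which is the least number that the bound, set after results had been seen, allowed, and of the 15 genes with more than 3 reads in either library 12 did, with a median distance of log2 2.51 over these 15 (Hal at 0.132 against 18.4 CPM and Gdpd3 at 1.06 against 333, with Cldn1 at 9.79 against 3.37 the farthest the other way). The heat shock gene Hspa1b, whose reads Hspa1a can share, was at 392 CPM in WT LPS replicate 1. In the other LPS libraries it was at most at 27.9. The chaperone gene Hspa5 was at 4818 CPM in KO LPS replicate 2 and 3750 in WT LPS replicate 1. It was at 1320.4 in KO LPS replicate 1 and 688 in WT LPS replicate 2, so this split ran across the genotypes. Both genes were chosen after their values were seen. They leave a difference in cell state between cultures as an open explanation that may be technical, and no biological explanation was tested.

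Some genes differed between genotypes in both treatments. At an unadjusted edgeR p under 0.01 in each, 35 genes had the same sign, 16 higher and 19 lower in KO, and 2 had opposite signs, where independence would give 2.88 of the same sign. Hal, a histidine-degrading enzyme gene chosen after its values were seen, was at 41.0 and 34.9 CPM in KO and 3.28 and 2.97 in WT at steady state, and at 25 and 18.4 in KO and 0.132 and 0.0619 in WT with LPS (edgeR adjusted p = 0.0726 and 0.00548). Segments of another mouse strain in one genotype could produce such differences and cannot be told apart from the genotype, since the 35 genes made 5 pairs within 5 Mb, a count inside the range of 10000 random sets (median 3, 5th to 95th percentile 1 to 7, 27.5% at or above 5). Of the pairs, 3 came from Cd1d2, Nes and Apoa1bp, which start between 86986586 and 88056520 on chromosome 3, and clustered or scattered strain differences and the genotype itself stay open.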
